A study of Homo sapiens with 6 samples.

How the data were processed

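RNA was measured in 6 libraries that the labels assign to HaCaT, an established line of immortalised human keratinocytes. The identity of the line was taken from the labels and was not tested. The titles and the treatment label put 3 libraries in a group named NC and 3 in a group named si-YTHDF2, the usual notation for cells given a small interfering RNA against YTHDF2. YTHDF2 encodes a cytoplasmic protein that binds N6-methyladenosine (m6A) in mRNA and recruits the deadenylation machinery. Per the labels, total RNA was taken up in Trizol, ribosomal RNA was depleted, and libraries were made with a low-input kit from GenSeq. The labels give each library a replicate number from 1 to 3 but do not say whether the numbers stand for separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

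Per the file headers, the deposited table holds a raw count per gene and library, and the authors made these counts before deposit. The submitters' processing notes name the genome build hg38; the aligner, the counting program and the use of strand are not given in the sources used here. The names of the count columns carry the word Input, which the labels do not explain. A further 6 columns, which the header describes as normalized by edgeR, were not used here. The table lists 16551 genes, all of them protein-coding by its own biotype column, each with a total of at least 1 count, and no line lacks a gene name. Noncoding RNAs were therefore not analysed here. For 12 symbols with a second gene identifier the identifiers were kept as separate genes, the one with fewer counts under its identifier, and 2 lines without an identifier were not used here. Gene positions, transcript lengths and 3-prime UTR sequences came from the GENCODE 29 annotation of GRCh38, which was matched by identifier for 16437 of the genes.

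The total count per library ran from 19803707 to 22698069. With counts of this size the spread between libraries exceeded counting error: chi-square per gene ran from 3.92 to 15.2 between libraries of a group, so no library repeated another within sampling noise. Between groups it ran from 95.2 to 107. In the si-YTHDF2 group replicate 1 stood apart, at 13.7 and 15.2 against replicates 2 and 3, which gave 3.92 between them. By Pearson correlation of log2 CPM the NC libraries were the less alike. It ran from 0.9845 to 0.9897 within NC and from 0.9908 to 0.9924 within si-YTHDF2. Low-count genes have the least precision, and genes that share sequence with near-identical copies (the alpha globins, replication-dependent histones, keratins, metallothioneins and SERPINB3 with SERPINB4) have uncertain counts because the authors' treatment of shared reads is unknown.

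The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM factors, the default filterByExpr filter, which left 12264 genes, and no covariate. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Levels are CPM, the library-size-scaled counts that edgeR returns with TMM factors, given as mean ± SD over the 3 libraries of a group. For YTHDF2 alone an exact permutation test was run as well; 3 libraries against 3 allow no p below 0.1.

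The gene lists, the tests of genes and lists, the alternatives other than a length and GC correction, and the rule for named genes were fixed before the data were examined. So were the comparison with other splits of the libraries and a test of GGACU motifs, while the tests of other explanations were chosen later. There were 31 lists, of which 29 had at least 3 tested members; the melanocyte list kept 2 (MITF and PMEL) and the list of noncoding RNAs kept 0. Each was tested with camera (limma 3.58.1), two-sided, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera asks whether a list moved relative to the other genes. It was repeated with an estimated correlation, which allows for the members' shared variation, and fry was run as a rotation test of whether a list's own genes move, on balance, one way. The named genes, apart from any not reported here, are YTHDF2, the 10 largest changes in each direction among called genes with non-overlapping groups and a mean log2 CPM of at least 1, the 4 members of each list with the smallest p, and a fixed set of m6A, Wnt, proliferation, keratin and inflammatory genes. Further genes named as members of a list were chosen after their values were seen, and each was recomputed under the alternatives.

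The alternatives were the RLE, upper-quartile and no composition factors, DESeq2 1.42.0, limma-voom, no low-count filter, a mean count of at least 50, other thresholds, the replicate number as a block, and leaving out each library in turn. Removal of a per-library trend with transcript length and GC content was added after the data were seen, as was a camera test of 249 KEGG pathways of 10 to 500 tested genes, assigned as in the deposited table. The test was checked on simulated counts with the real means and depths: of 66 genes changed by 0.5 on the log2 scale it recovered 75.8%, of 66 changed by 1 it recovered 89.4%, and of 66 changed by 2 it recovered 98.5%, with 10 calls among 11973 unchanged genes, in a step on 12171 genes. The simulated genes took their spread from the trend over expression, without a spread of their own. Far fewer of them changed than were called in the real data, so these rates may not hold there. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.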

Results

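Expression was compared between 3 NC and 3 si-YTHDF2 libraries labelled as HaCaT keratinocytes, in a series whose title names proliferation, the inflammatory response and Wnt signaling in psoriasis. The NC libraries held 22133115, 20312740 and 22698069 counts and the si-YTHDF2 libraries 21481302, 21269464 and 19803707. Between 14547 and 14990 genes had a count in a library. The first principal component of log2 CPM carried 69.5% of the variance and separated the groups. The second carried 11.6% and spread the NC libraries from -20.2 (replicate 3) to 27.0 (replicate 1). On it the si-YTHDF2 libraries lay between -2.01 and 2.43.

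YTHDF2 itself (ENSG00000198492), the m6A reader targeted here, was lower in each si-YTHDF2 library than in any NC library. The gene lies on the plus strand of chromosome 1 from 28736621 to 28769775 in GRCh38. Its level was 78.7 ± 4.72 CPM in NC (SD, n = 3) and 44.9 ± 2.98 CPM in si-YTHDF2 (SD, n = 3), which left 57.1% of the NC level. The log2 fold change was -0.81 with a standard error of 0.07 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.13e-07). The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. Of its paralogs, YTHDF1 was higher by a log2 fold change of 0.26 (edgeR, adjusted p = 0.00123), while YTHDF3 had a log2 fold change of 0.01 ± 0.07 (SE; edgeR, adjusted p = 0.910), which was -0.02 without NC replicate 1 and -0.08 without si-YTHDF2 replicate 1.

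**Figure D1:**
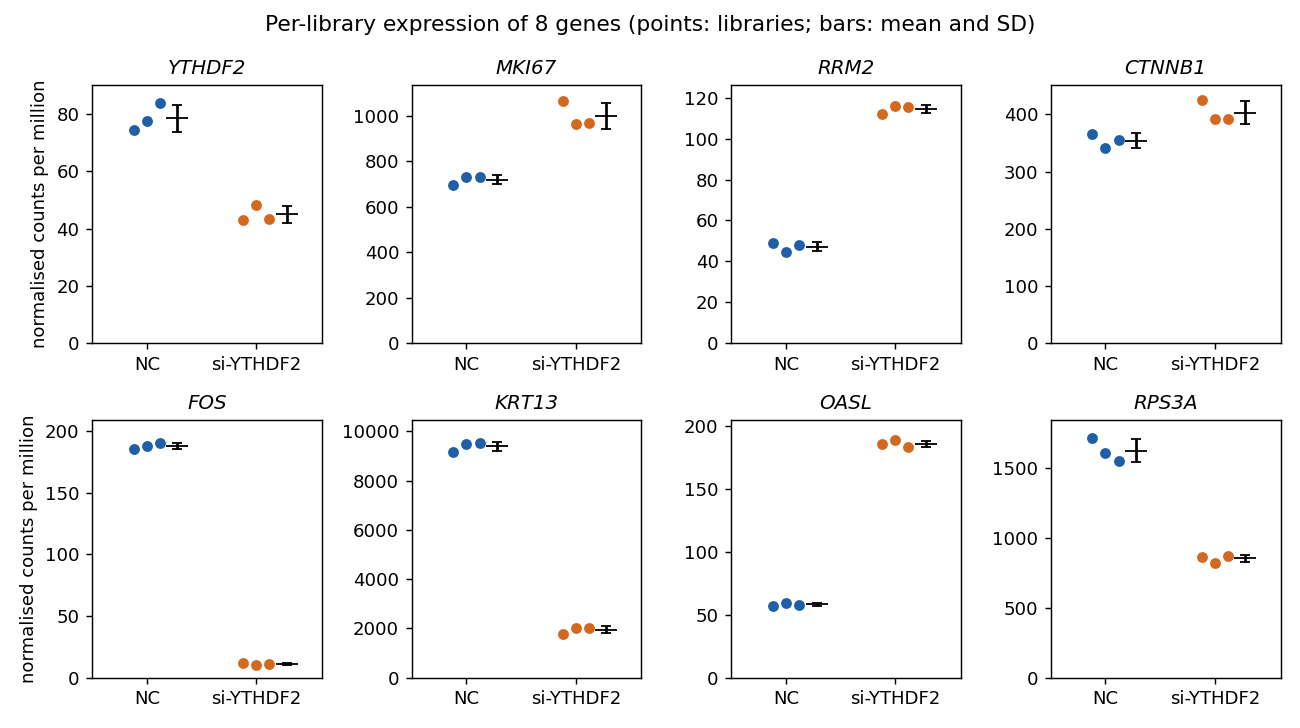
Normalised CPM of 8 genes on linear axes that start at 0; points are the 3 libraries of each group, and the black bars give their mean and SD. The YTHDF2 libraries average 78.7 CPM in NC and 44.9 CPM in si-YTHDF2, and in none of the 8 genes do the groups overlap.

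The other transcripts of the m6A machinery moved little and in both directions. Of 23 tested members of the m6A list 5 were higher, 7 lower and 11 not past the threshold, with the same counts adjusted over the list alone. The eraser FTO fell (log2 fold change -0.40; edgeR, adjusted p = 2.78e-04), as did the readers IGF2BP2 (-0.44) and IGF2BP3 (-0.39), the writer METTL3 (-0.26) and its cofactor ZC3H13 (-0.45). The eraser ALKBH5 rose (0.31), and METTL14 had a log2 fold change of -0.08 (edgeR, adjusted p = 0.416). Among 30 tested genes of deadenylation and mRNA decay 2 were higher and 10 lower, also adjusted over the list alone. BTG2, which recruits the CCR4-NOT deadenylase, fell by 1.89 on the log2 scale, the poly(A)-binding protein PABPC1 by 0.56 and TOB2 by 0.43, while the CNOT9 subunit rose (0.45). Of 27 tested transcripts listed as YTHDF2-bound in the literature, 9 were higher, 9 lower and 9 not past the threshold, the same adjusted over the list alone. In that list IGFBP3 fell from 1262 to 235 CPM (log2 fold change -2.42) and MYC fell by 0.77, whereas MAP4K4 (0.55) and CCNA2 (0.68) rose. None of these 3 lists was called by camera (adjusted p = 0.704 for m6A, 0.219 for decay and 0.831 for the YTHDF2-bound list). The decay list was called with DESeq2 (camera, adjusted p = 0.0236), the lowest over its alternatives, which reached 0.385.

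Across the transcriptome 6285 of 12264 genes differed, 3199 higher and 3086 lower in si-YTHDF2 (edgeR, adjusted p under 0.05). With library totals in place of TMM factors 3860 were higher and 2433 lower, which moved the share of higher calls from 50.9% to 61.3%. Most changes were small: 4219 of the 6285 were under 1.5-fold, and 907 reached 2-fold, 433 higher and 474 lower. The groups did not overlap in 7178 genes, 58.5% of those tested, where chance gives 10%.

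The largest increases were dominated by transcripts of blood cells. HBB, the beta chain of hemoglobin, rose from 46.6 ± 1.70 to 1412 ± 120 CPM (SD, n = 3 each), a log2 fold change of 4.92 ± 0.07 (SE; edgeR, adjusted p = 1.09e-14). The alpha globin genes HBA1 and HBA2, which share nearly identical sequence, rose by log2 fold changes of 4.40 and 4.41. ALAS2, the erythroid enzyme that begins heme synthesis, rose from 0.160 to 7.90 CPM, and the erythroid gene HEMGN and the platelet chemokine PPBP rose by 5.17 and 4.43 on the log2 scale. The other 4 of the 10 were the homeobox gene NKX1-2 (5.03, and 5.70 without NC replicate 3), SYT14 (4.55), FCRLA and NT5DC4. Whether any of these 4 also came from blood cells was not examined. FCRLA had 3, 2 and 3 counts in NC and 147, 160 and 118 in si-YTHDF2, and NT5DC4 had 3 in each NC library and 118, 113 and 144 in si-YTHDF2. Apart from the globins, these genes had low levels in both groups, with 7.90 CPM for ALAS2 as the highest.

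The large decreases included genes of much higher abundance. KRT4, a keratin of mucosal epithelium, fell from 500 ± 4.15 to 8.53 ± 1.71 CPM (SD, n = 3 each; log2 fold change -5.88; edgeR, adjusted p = 2.35e-14). ID1, an inhibitor of helix-loop-helix transcription factors, fell from 582 to 33.1 CPM (-4.14), and FOS, an AP-1 subunit, from 188 to 11.2 CPM (-4.08). The GABA receptor subunit GABRP fell by 5.41 on the log2 scale, and BPIFB1, a secretory gene of the airways, fell from 47.4 to 1.74 CPM. SYTL5 (-4.37), RGS16 (-4.06), the immune checkpoint ligand VTCN1 (-3.92) and IDO1, which degrades tryptophan (-3.90), fell as well. Non-overlapping groups and a call were conditions for naming the large increases and decreases here. Each of these genes kept its direction and its call under every alternative that tested it, of which there were 14 or 15 per gene.

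**Figure D2:**
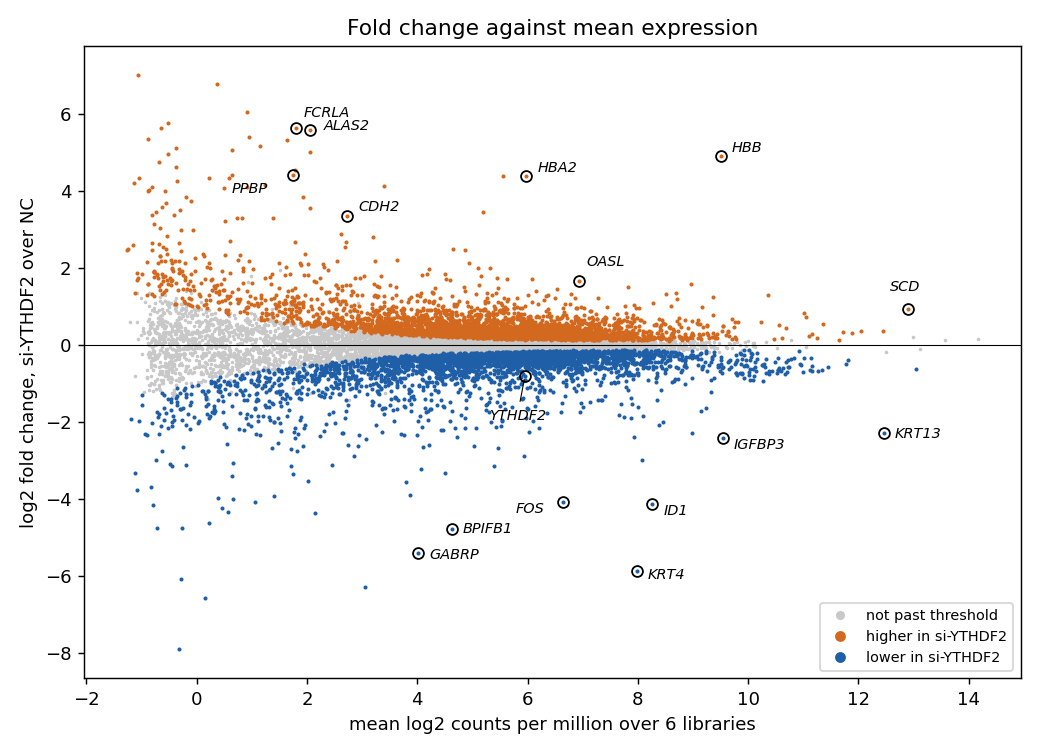
Log2 fold change of si-YTHDF2 over NC against mean log2 CPM for the 12264 genes tested; orange and blue points passed an adjusted p of 0.05 (edgeR) and circles mark named genes. HBB at 4.92, KRT4 at -5.88, ID1 at -4.14 and FOS at -4.08 lie far outside the band of most genes.

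Proliferation was examined through lists of replication and mitosis genes. In si-YTHDF2, 33 of 45 genes of G2/M and mitosis were higher and 0 were lower; adjusted over the list alone the counts were 35 and 1. The proliferation marker MKI67 rose from 720 ± 19.9 to 1000 ± 55.8 CPM (SD, n = 3 each), and FOXM1 (log2 fold change 0.85), which drives mitotic transcription, the kinesins KIF2C (0.55) and KIF23 (0.52) and the kinase AURKA (0.47) rose as well. Of 46 genes of G1/S and DNA replication 31 were higher and 3 lower, also adjusted over the list alone. RRM2, a subunit of ribonucleotide reductase, rose by 1.28, CDC45 by 0.91, FEN1 by 0.74 and EXO1 by 0.69, while POLA1 (-0.48), UNG (-0.30) and MCM6 (-0.15) fell. The call of MCM6 was lost without NC replicate 1 (edgeR, adjusted p = 0.107), NC replicate 3 (0.0866), si-YTHDF2 replicate 2 (0.0835) or si-YTHDF2 replicate 3 (0.0790), and with library totals (0.220). The median log2 fold change was 0.32 for G2/M (camera, adjusted p = 1.39e-06) and 0.29 for G1/S (camera, adjusted p = 1.18e-05). With an estimated correlation neither call held (adjusted p = 0.185 for G2/M and adjusted p = 0.175 for G1/S).

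Replication-dependent histone transcripts went the other way. Of 45 tested histones 28 were lower and 5 higher (6 higher adjusted over the list alone), with a median of -0.22 (camera, adjusted p = 7.19e-04; adjusted p = 0.877 with an estimated correlation). HIST1H4B fell from 380 to 205 CPM, HIST1H2AI by 0.88, HIST1H3I by 0.73 and HIST1H1D by 0.62 on the log2 scale. These genes are close copies of each other, so the split between members is uncertain. Cell cycle inhibitors and p53 targets moved in both directions: 10 of 29 were higher and 8 lower, the same adjusted over the list alone (camera, adjusted p = 0.831). AEN (1.25) and the apoptosis gene BAX (0.62) rose, and BTG2 (-1.89) and ZMAT3 (-0.72) fell.

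Wnt signaling components did not move together. Of 52 ligands, receptors and transducers 17 were higher and 18 lower (17 and 19 adjusted over the list alone), with a median log2 fold change of -0.01 (camera, adjusted p = 0.949). The secreted antagonist-family gene DKK3 rose from 11.4 ± 0.50 to 36.7 ± 1.35 CPM (SD, n = 3 each; log2 fold change 1.69; edgeR, adjusted p = 1.95e-09), and the transducer DVL2 rose by 0.54. The ligand WNT10A fell from 44.3 to 21.2 CPM (-1.06) and the corepressor TLE2 from 12.7 to 2.49 CPM (-2.34). CTNNB1, which encodes beta-catenin, rose by 0.19 (edgeR, adjusted p = 0.00883), a call that was lost without NC replicate 2 (0.16; adjusted p = 0.0545), with adjusted p from 7.53e-05 over the alternatives.

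Target genes of beta-catenin likewise divided. Of 27 tested, 13 were higher and 8 lower, the same adjusted over the list alone. The median was 0.26 (camera, adjusted p = 0.313, and 0.764 with an estimated correlation). It ran from 0.13 to 0.32 over 15 alternatives at the preset correlation, none of which gave a call. CCND1, the G1 cyclin D1, rose from 407 to 558 CPM (0.46), SOX9 rose by 1.33 and VEGFA by 1.16. MYC fell from 254 to 148 CPM (-0.77), JUN by 1.23 and the protease gene MMP7 by 1.56. AXIN2, a widely used readout of the pathway, lay below the low-count filter, with counts of 14, 7 and 9 in NC and 0, 2 and 3 in si-YTHDF2.

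Inflammatory transcripts changed gene by gene. Among 25 psoriasis-associated keratinocyte genes 7 were higher, 8 lower and 10 not past the threshold (8 higher and 8 lower adjusted over the list alone). LCN2, an antimicrobial siderophore binder, rose from 383 ± 4.99 to 758 ± 55.1 CPM (SD, n = 3 each; log2 fold change 0.99; edgeR, adjusted p = 9.11e-09), S100A7 rose by 1.14 and S100A8 by 1.94, the last from 0.698 to 2.68 CPM. S100A9 fell (-0.39), as did the hyperproliferation keratin KRT6A (-1.53), the vitamin B12 binder TCN1 (-2.65) and the protease inhibitor SERPINB4 (-2.75). S100A8 is also abundant in blood neutrophils and monocytes. Of 11 myeloid markers with at least 10 counts over the 6 libraries, 8 were higher in si-YTHDF2, S100A8 among them (edgeR without a low-count filter). CD14 and CLEC7A were lower. The list's median was 0.15 and its mean -0.02, and camera gave no call (adjusted p = 0.942). KRT16 had counts of 9 to 22 and KRT17 of 43 to 69 in the 6 libraries, and neither differed (edgeR, adjusted p = 0.0601 and 0.635); KRT16 was called with library totals (0.99; adjusted p = 0.0433, with up to 0.179 over the alternatives). KRT17 had a log2 fold change of 0.15, and of -0.04 without NC replicate 1.

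Of 23 cytokine and chemokine genes 5 were higher and 5 lower, the same adjusted over the list alone (camera, adjusted p = 0.686). The death ligand gene TNFSF10 fell from 408 to 78.4 CPM (-2.38) and CCL22 by 1.09, whereas the monocyte chemokine CCL2 rose from 23.0 to 51.4 CPM (1.16) and LIF by 1.35. IL6 and CXCL8 were near 0.5 to 3 CPM and did not pass the test (log2 fold changes -0.52 and 0.30; edgeR, adjusted p = 0.385 and 0.330). In the NF-kB list 13 of 38 genes were higher and 18 lower (14 and 18 adjusted over the list alone; camera, adjusted p = 0.313). TNFAIP2 fell from 909 to 295 CPM, the inhibitor of apoptosis BIRC3 by 1.37 and the IL-1 receptor IL1R1 by 1.31, and the receptor kinase IRAK1 rose by 0.61. Among 36 genes of IL-17, IL-22 and JAK-STAT signaling 5 were higher and 13 lower, the same adjusted over the list alone (median -0.10; camera, adjusted p = 0.0856). The receptor subunit IL20RB fell by 1.98, IL13RA1 by 0.44 and the kinase JAK1 by 0.43, and the feedback inhibitor SOCS3 was 3.03-fold lower. That list was called without NC replicate 2 (-0.14; adjusted p = 0.0480), with no low-count filter (adjusted p = 0.0446), with DESeq2 (adjusted p = 0.0414) and after removal of a length and GC trend (adjusted p = 0.0377), and reached 0.129 over the alternatives.

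Interferon-stimulated genes rose as a list. Of 42 tested 28 were higher and 6 lower, also adjusted over the list alone, with a median of 0.44 (camera, adjusted p = 9.02e-05; adjusted p = 0.175 with an estimated correlation). OASL rose from 58.3 ± 1.20 to 186 ± 2.56 CPM (SD, n = 3 each), IFI6 from 31.4 to 104 CPM and RSAD2, which encodes the antiviral enzyme viperin, from 7.84 to 28.2 CPM. ISG15 (1.71) and MX1 (1.36) rose too. IRF1, a transcription factor of the interferon response, fell from 337 to 131 CPM (-1.36), and SAMD9L (-1.61) and SAMD9 (-1.22) fell with it.

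In the keratinocyte differentiation list more genes were lower than higher. Of 33 tested 16 were lower, 2 higher and 15 not past the threshold, also adjusted over the list alone. KRT13, among the most abundant transcripts of the table, fell from 9391 ± 192 to 1941 ± 136 CPM (SD, n = 3 each; log2 fold change -2.27; edgeR, adjusted p = 9.19e-13). KRT4 fell as given above, NOTCH3 by 1.96, the cornified envelope genes TGM1 by 1.86 and IVL by 1.39, and CSTA by 0.90, while ALOX12B (1.48) and KLF4 (0.48) rose. ALOX12B was not called without NC replicate 1 (1.16; edgeR, adjusted p = 0.0597) or si-YTHDF2 replicate 2 (0.86; edgeR, adjusted p = 0.178). The list median was -0.40 (camera, adjusted p = 0.0126; adjusted p = 0.716 with an estimated correlation). It came to -0.69 without NC replicate 1, -0.14 with limma-voom and -0.14 with the replicate block, and without NC replicate 3 it was -0.07 and not called (adjusted p = 0.254, the highest over the alternatives, where the lowest was 4.10e-06).

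The basal keratinocyte and hemidesmosome list divided, with 6 of 22 higher and 7 lower, the same adjusted over the list alone (camera, adjusted p = 0.624). The basal keratin KRT5 was abundant and rose slightly, from 2029 to 2384 CPM (log2 fold change 0.23; edgeR, adjusted p = 0.00250), and the hemidesmosomal collagen COL17A1 rose by 0.64. KRT15 fell from 865 to 264 CPM (-1.71), ASS1 by 1.86 and DLK2 by 1.01. KRT14, the usual partner of KRT5, had counts of only 12 to 98 per library and did not differ (log2 fold change -0.15; edgeR, adjusted p = 0.820). The simple-epithelium keratins KRT7 and KRT19 averaged 1835 and 1999 CPM over the 6 libraries, against 2.11 CPM for KRT14. Without NC replicate 3, which held the 98 counts, its log2 fold change was 0.86 (edgeR, adjusted p = 0.114). The basal list was called with DESeq2 (camera, adjusted p = 0.0228), the lowest over its alternatives, which reached 0.918.

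Immediate early genes fell on balance. Of 31 tested 18 were lower and 9 higher (18 and 10 adjusted over the list alone), with a median of -0.65 (camera, adjusted p = 0.00603; adjusted p = 0.461 with an estimated correlation). FOSB fell from 75.4 to 8.60 CPM, EGR1 from 108 to 22.8 CPM, JUNB from 315 to 88.8 CPM and the phosphatase gene DUSP1 by 1.94. The AP-1 subunits FOSL1 (1.27) and JUND (0.55) rose. Of 34 genes of the unfolded protein and integrated stress response 7 were higher and 12 lower (8 and 12 adjusted over the list alone; camera, adjusted p = 0.704), among them EDEM1 (1.03), DDIT3 (1.03), DDIT4 (-0.85) and ATF3 (-1.13). Of 14 heat shock genes 5 were higher and 6 lower, the same adjusted over the list alone (camera, adjusted p = 0.831): the autophagy receptor SQSTM1 rose from 391 to 932 CPM and the chaperone HSPA8 by 0.45, while HSPB1 (-0.68) and HSPD1 (-0.73) fell. In the NRF2 list 14 of 22 were higher and 5 lower, the same adjusted over the list alone (median 0.28; camera, adjusted p = 0.115). AKR1C1 (1.13) and AKR1C2 (1.04) rose and the metallothioneins MT1X (-1.72) and MT1E (-1.20) fell. The NRF2 list was called with DESeq2 (camera, adjusted p = 0.0108) and with limma-voom (camera, adjusted p = 0.0414), and its adjusted p reached 0.178 over the alternatives.

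In the lipid synthesis list and in the hypoxia and glycolysis list more genes were higher than lower. Of 33 genes of cholesterol and fatty acid synthesis 24 were higher and 4 lower, also adjusted over the list alone, with a median of 0.43 (camera, adjusted p = 1.10e-05; adjusted p = 0.175 with an estimated correlation). The desaturase SCD rose from 5209 ± 110 to 10041 ± 277 CPM (SD, n = 3 each), fatty acid synthase FASN from 755 to 1883 CPM, the sterol isomerase EBP from 83.3 to 167 CPM and the transcription factor SREBF1 by 1.20 on the log2 scale. In the hypoxia and glycolysis list 23 of 34 were higher and 3 lower, also adjusted over the list alone, with a median of 0.50 (camera, adjusted p = 5.38e-05; adjusted p = 0.175 with an estimated correlation). PDK1, which restrains pyruvate oxidation, rose from 9.77 to 35.6 CPM, the glucose transporter SLC2A1 from 47.6 to 118 CPM, the aldolase ALDOC by 1.31 and VEGFA by 1.16. PFKFB3 fell (-0.67), and the hypoxia marker CA9 had a log2 fold change of -0.13 that did not pass the test.

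Transcripts of cytosolic ribosomal proteins were lower almost throughout. Of 74 tested 72 fell and 0 rose, also adjusted over the list alone, with a median log2 fold change of -0.57 (camera, adjusted p = 2.54e-21; adjusted p = 0.309 with an estimated correlation). RPS3A fell from 1623 ± 81.6 to 852 ± 26.0 CPM (SD, n = 3 each), RPL9 from 1399 to 804 CPM, RPL4 from 3143 to 2020 CPM and RPLP0 from 2709 to 1738 CPM. Together the 74 genes took 9.41% of the counts in NC and 6.60% in si-YTHDF2. Nuclear-encoded genes of oxidative phosphorylation had a median of 0.04, with 15 of 49 higher and 6 lower (15 and 5 adjusted over the list alone; camera, adjusted p = 0.422). CYCS, which encodes cytochrome c, rose by 0.53 and UQCRFS1 by 0.43, and UQCRB fell by 0.43. Of 13 mitochondrially encoded mRNAs 7 were higher and 0 lower, also adjusted over the list alone (median 0.29; camera, adjusted p = 0.141), with MT-ND1 at 1490 ± 177 CPM in NC and 2676 ± 462 CPM in si-YTHDF2 (SD, n = 3 each). The list was called without si-YTHDF2 replicate 1 (0.43; adjusted p = 0.0120), with limma-voom (adjusted p = 0.0414) and with the replicate block (adjusted p = 0.0482), and reached 0.385 over the alternatives.

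Matrix and mesenchymal genes showed opposite changes within the list. Of 33 genes 12 were higher and 7 lower, the same adjusted over the list alone (camera, adjusted p = 0.532). The cadherin CDH2 rose from 1.17 to 11.9 CPM (3.35) and thrombospondin THBS1 from 234 to 597 CPM (1.35), whereas the collagenase MMP13 (-2.67) fell from 76.3 CPM and the protease inhibitor TIMP3 fell from 427 to 119 CPM (-1.85).

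Markers of other cell types were also followed. In the immune and blood list 7 of 9 tested genes were higher and 2 lower, also adjusted over the list alone, with a median of 4.11 (camera, adjusted p = 0.00139; adjusted p = 0.175 with an estimated correlation). Besides the globins, the leukocyte gene PTPRC rose from 0.235 to 4.30 CPM and LYZ from 0.478 to 6.93 CPM, while CD74, the MHC class II invariant chain, fell from 36.1 to 7.89 CPM and CD14 from 3.19 to 1.93 CPM. The call of CD14 was lost without NC replicate 2 (edgeR, adjusted p = 0.0918), si-YTHDF2 replicate 1 (0.0827) or si-YTHDF2 replicate 3 (0.0576). Of 11 fibroblast genes 0 were higher and 1 lower, also adjusted over the list alone (camera, adjusted p = 0.704): FBLN1 fell by 1.08. LUM (-0.94), COL1A1 (-0.24) and DCN (-0.68) did not pass the test (edgeR, adjusted p = 0.120, 0.203 and 0.309). DCN stood at 201 counts in NC replicate 1 against 31 and 33 in the other NC libraries, and without that library its log2 fold change went from -0.68 to 0.73. Without NC replicate 3 LUM (-1.30; edgeR, adjusted p = 0.0309) and COL1A1 (-0.40; edgeR, adjusted p = 0.0272) were called, with adjusted p up to 0.744 and 0.672 over their alternatives. LUM had a log2 fold change of -0.21 without NC replicate 1. In the endothelial and simple-epithelium list of 8 genes 1 was higher and 3 lower, also adjusted over the list alone (median 0.13 and mean 0.08 against a camera direction of down; adjusted p = 0.877). The simple-epithelium keratins KRT19 (-0.52), KRT8 (-0.36) and KRT18 (-0.26) fell, the last pair lying on overlapping stretches of chromosome 12, and CDH5 rose by 0.27. Of the melanocyte list, MITF fell by 0.23 (edgeR, adjusted p = 0.0306), a call lost without NC replicate 1, NC replicate 3 or si-YTHDF2 replicate 3 (adjusted p = 0.0511, 0.145 and 0.0896), with library totals, with DESeq2 and after removal of a length and GC trend (0.109, 0.0553 and 0.0620), and PMEL had a log2 fold change of 0.25 (edgeR, adjusted p = 0.449).

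**Figure D3:**
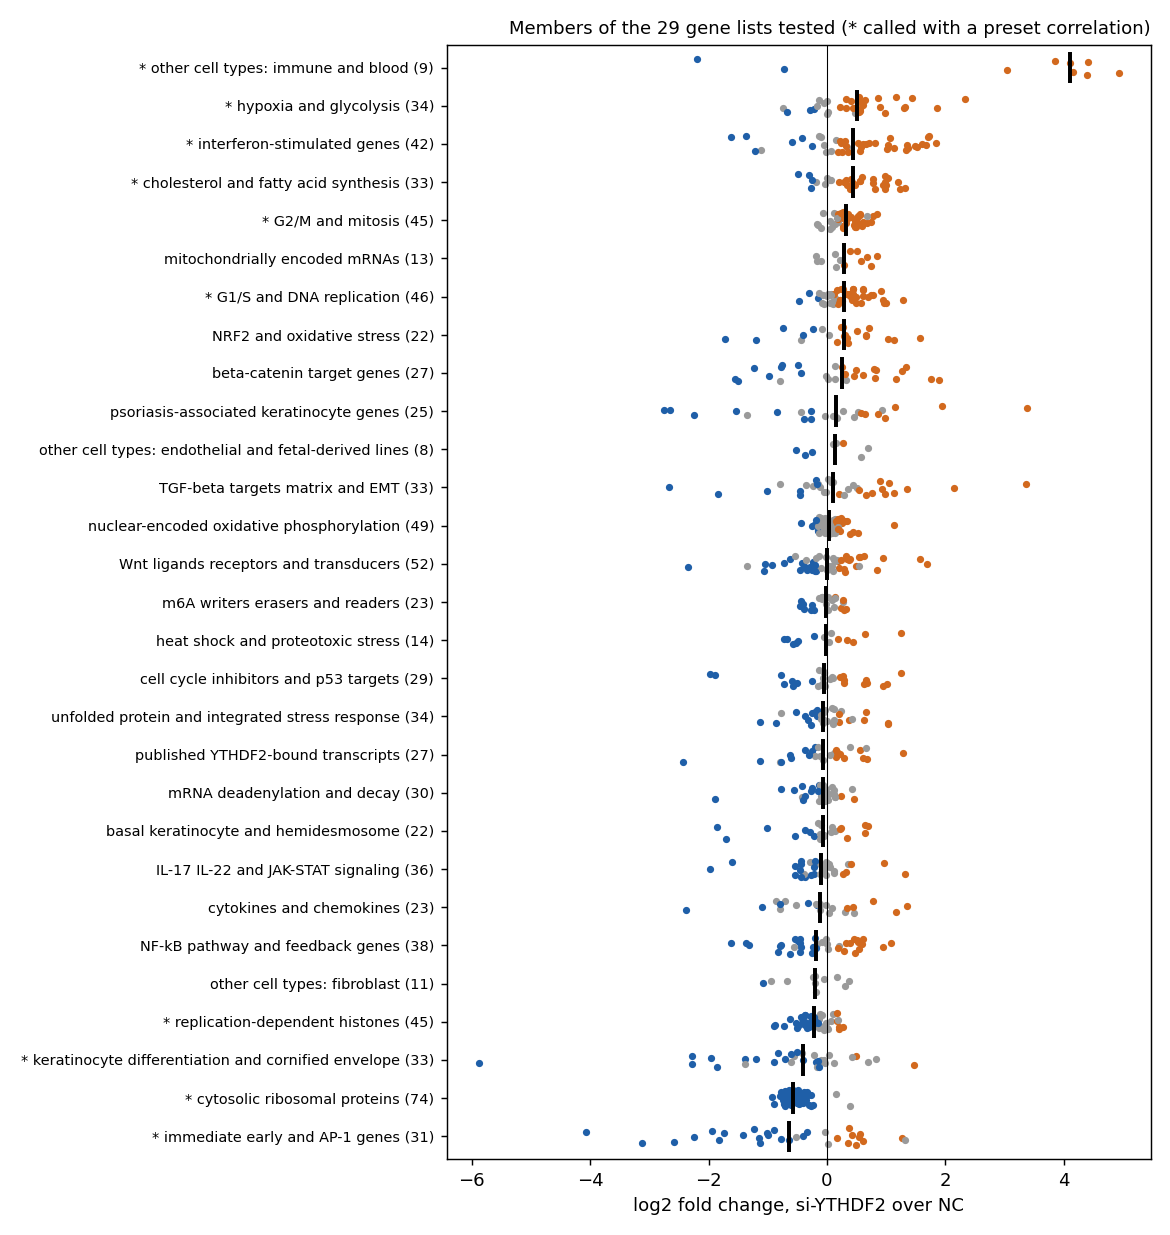
Log2 fold change of si-YTHDF2 over NC for each tested member of the 29 gene lists, with the number of members in parentheses; orange and blue points passed an adjusted p of 0.05 (edgeR), grey points did not, and the black bar is the list median. Lists with a star were called by camera with a preset correlation: the ribosomal proteins centre on -0.57 and the immune and blood list on 4.11.

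Of the 29 lists 10 were called with the preset correlation, 6 upward and 4 downward. With an estimated correlation camera called 0 of the 29, with 6 at an unadjusted p under 0.05 and a smallest adjusted p of 0.175, and fry called 19. Fry kept 9 of the 10 calls and lost that of the histones (fry, adjusted p = 0.0502), and it called the YTHDF2-bound list downward (fry, adjusted p = 1.57e-04), of which 9 genes were higher and 9 lower. Fry's direction differed from camera's for the heat shock list (up against down) and for the psoriasis list (down against up).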

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

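The removal of a length and GC trend and the KEGG pathways were chosen after the data were seen; the other alternatives were planned. With 3 libraries per group, small differences in genes of low counts are the least certain. The count of genes differing (6285, edgeR) was 6267 with RLE factors, 6287 with upper-quartile factors, 6293 with library totals, 6078 with DESeq2, 6344 with limma-voom, 6411 without a low-count filter, 5950 at a mean count of at least 50, 5496 to 6757 with a library left out, and 6918 after removal of the length and GC trend. The highest count with a library left out, 6757, came without si-YTHDF2 replicate 1. The count was 907 when a fold change of at least 2 was also required, by construction. With the replicate number as a block it was 6438, of which 6203 were shared. The same-number correlations of deviations were 0.0553, 0.0524 and 0.0349, each above every different-number one (-0.0489 to 0.0069). They were small, so the numbers were not treated as pairs in the main test, but a weak shared origin is not excluded. No called gene changed sign, except 1 each without NC replicate 1, NC replicate 2 and si-YTHDF2 replicate 2. The fall of YTHDF2 kept its call under all 15 alternatives (-0.86 to -0.74). An alternative restricted to protein-coding genes removes no gene and was not run, and those for normalised values do not apply.

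Camera called 10 of 29 lists. With an estimated correlation it called 0 (6 at an unadjusted p under 0.05), where G1/S (0.2879) and G2/M (0.3241) lost their calls. Fry, which does not compare a list with other genes, called 19. It lost the histones (-0.224) and gained, among others, beta-catenin targets upward (0.2566) and cytokines (-0.1126) and NF-kB (-0.1777) downward. The psoriasis-associated genes were gained as well, called downward by fry although their median was 0.1514. Camera's direction reversed, without a call and on list medians near 0, for Wnt components with DESeq2 (median -0.0676), limma-voom (-0.0065) and a mean count of at least 50 (0.0647) and without si-YTHDF2 replicate 1 (-0.0143), with medians of -0.0266 to -0.0062 when a library was left out. It reversed for the psoriasis list with library totals (0.2184), DESeq2 (0.355), limma-voom (0.1764) and a mean count of at least 50 (-0.0291), and without si-YTHDF2 replicate 1 (0.0984) or 3 (0.1376), with medians of 0.0271 to 0.1919 when a library was left out. For heat shock it reversed with DESeq2 (-0.096) and without si-YTHDF2 replicate 2 (0.0396), and fry gave the other direction (-0.0088), with medians of -0.1456 to 0.0956 when a library was left out. It reversed without NC replicate 1 for the fibroblast list (medians of -0.4692 to 0.0721 when a library was left out), and without NC replicate 1 or 2 for the endothelial list (-0.0952 to 0.2252). With a library left out DCN ran from -1.0854 to 0.7339, YTHDF3 from -0.081 to 0.0716, KRT14 from -0.6196 to 0.8574, KRT17 from -0.045 to 0.2797, KRT1 from -0.793 to 2.06 and TRIM69 from -0.8956 to 3.4877. YTHDF3 was at -0.0039 after removal of the length and GC trend, and with limma-voom and with the block KRT14 was at 0.3048 and 0.1606 and KRT1 at 1.7618 and 0.717. The cause was not tested for any of these.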

Other observations

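Of the tests below, the split of libraries and the GGACU test were planned, and the other tests and the gene groups were chosen only after the result was seen. A group of 12 genes of mucosal and secretory epithelium, picked because members were among the largest decreases, was lower throughout (edgeR). Beside KRT4, KRT13 and BPIFB1 it held the club-cell secretoglobin SCGB1A1 (log2 fold change -2.98), the water and glycerol channel AQP3 (-2.88), the disulfide isomerase AGR2 (-2.62), the mucins MUC16 (-2.27) and MUC1 (-0.96) and the epithelial transcription factors ELF3 (-2.01) and GATA3 (-1.74). The 4 tested genes of an MHC class II group fell as well: CD74 by 2.19, HLA-DRB1 by 2.07, HLA-DRB5 by 2.03 and their activator CIITA by 1.36 on the log2 scale. The wider KEGG pathway of antigen processing and presentation was not called, with 10 of 32 genes lower and 2 higher (camera, adjusted p = 0.386). HLA-DRB1 and HLA-DRB5 share sequence, so the split between them is uncertain. A group of 10 genes of BMP signaling and its ID targets divided, with 2 higher and 5 lower (edgeR). The helix-loop-helix inhibitors ID1, ID2 (-1.50) and ID3 (-2.15) fell, and the ligand BMP2 (1.27) and the antagonist FST (5.65-fold) rose. BMP4 (-0.61) and the receptor BMPR2 (-0.21) were also lower. The call of BMP4 was lost without NC replicate 2 or 3 or si-YTHDF2 replicate 1 or 2 and with DESeq2 (adjusted p = 0.0544 to 0.0988), and that of BMPR2 without NC replicate 1 or 3 or si-YTHDF2 replicate 2 or 3 and with library totals (edgeR, adjusted p = 0.0559 to 0.127). ID4 (-1.29), SMAD6 (0.22) and SMAD7 (0.29) did not pass the test (edgeR, adjusted p = 0.122, 0.0846 and 0.253). Without si-YTHDF2 replicate 1 ID4 (-2.40; edgeR, adjusted p = 0.0207) and SMAD6 (0.29; edgeR, adjusted p = 0.0244) were called, and without NC replicate 1 ID4 was at -0.48. ID4 was also called with the replicate block (edgeR, adjusted p = 0.0342) and SMAD6 with library totals (edgeR, adjusted p = 0.0288).

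Of 249 KEGG pathways 5 were called (camera), and with an estimated correlation 0 were, with 12 at an unadjusted p under 0.05 and a smallest adjusted p of 0.749. Ribosome was lower, with 84 of 126 genes lower and 15 higher (camera, adjusted p = 5.39e-07), and so was estrogen signaling, with 15 of 23 lower (camera, adjusted p = 0.0322). Proteasome (24 of 38 higher), chondroitin and dermatan sulfate synthesis (8 of 17 higher) and glycosaminoglycan degradation (8 of 16 higher) rose (camera, adjusted p = 0.0328 each). Among the pathways not called was Wnt signaling, with 29 of 95 higher and 31 lower (camera, adjusted p = 0.974). Some pathways near other lists called in the report were not called. Cell cycle had 55 of 117 higher and 18 lower, and DNA replication 11 of 23 higher and 1 lower (camera, adjusted p = 0.0681 and 0.128). Steroid biosynthesis had 8 of 18 higher and 5 lower, and fatty acid biosynthesis 5 of 10 higher and 1 lower (camera, adjusted p = 0.452 and 0.572). Glycolysis and gluconeogenesis had 18 of 47 higher and 14 lower, and HIF-1 signaling 27 of 65 higher and 21 lower (camera, adjusted p = 0.684 and 0.784). Some genes varied within a group. The suprabasal keratin KRT1 stood at 0.229, 6.40 and 40.1 CPM in the NC libraries, and without NC replicate 3 its log2 fold change went from -0.21 to 2.06 (edgeR, adjusted p = 0.0110). TRIM69 stood at 30.3 CPM in si-YTHDF2 replicate 2 and at no more than 2.35 CPM elsewhere, and without that library its log2 fold change went from 2.90 to -0.90 (edgeR, adjusted p = 0.171). Its call was also lost without NC replicate 1 or 2 (edgeR, adjusted p = 0.0633 and 0.0904), with limma-voom (0.486) and with the replicate block (0.161). PSMB3 stood at 66.4, 9.14 and 126 CPM in si-YTHDF2 and at 5.31 to 6.66 CPM in NC, and without si-YTHDF2 replicate 3 its log2 fold change went from 3.47 to 2.64.

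The number of genes differing, 6285 in the real grouping (edgeR), was 0 in each of the other splits of the 6 libraries into 3 and 3, so 1 of 10 splits gave as many. In those others 54 to 217 genes had an unadjusted p under 0.05, and limma-voom called 0. The 10 splits are too few for a share under 0.05. Each of the other splits also mixed NC and si-YTHDF2 libraries, so the group difference entered the spread within each side. That spread lowers the number of calls, so these splits do not show what chance alone would give.

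Transcripts of blood cells were higher in si-YTHDF2 across lineages. If whole blood RNA were the source, platelet and white-cell markers would rise with the globins: among markers with at least 10 counts over the 6 libraries the lowest lineage median log2 fold change was 2.81, for myeloid markers (8 of 11 higher and 2, CD14 and CLEC7A, lower), against 3.02 for lymphoid (5 of 9 higher) and 3.21 for platelet markers (4 of 6 higher; edgeR without a low-count filter). That minimum leaves out markers low in both groups, and many of the rest had few counts; with every listed marker that had a count, and counts under 3 per group set to 3, the medians were 1.63 for lymphoid, 1.71 for platelet and 2.28 for myeloid markers, which is in line with blood RNA in the si-YTHDF2 libraries. A single blood source as the only origin of globin RNA in all 6 libraries would hold alpha and beta globin in 1 ratio. HBB, however, rose by 0.52 more than the alpha globins on the log2 scale (SE 0.0914). In NC the alpha globins had only 81 to 138 counts per gene and library. A little globin RNA of another origin there would also shift the ratio, so a shared source is not excluded. An effect of the knockdown on the blood-cell transcripts was not tested and stays open.

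Ribosomal protein mRNAs are short, and a yield that varied with length could lower them. After removal of a length and GC trend their median was -0.58, with 72 of 74 lower, which argues against that trend as the whole cause. Lengths were those of 1 annotated transcript per gene, which may not be the one expressed. Nuclear-encoded oxidative phosphorylation mRNAs are of similar length (median 1082 against 1029 nt). They had a median log2 fold change of 0.0388 with an SD of 0.245, which argues against a general loss of mRNAs of that length. The replication-dependent histone transcripts, which were also lower, were not part of this comparison. An effect of reduced YTHDF2 is a hypothesis that stays untested.

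KRT14, KRT16 and KRT17, abundant in cultured keratinocytes, had few counts in both groups. Reads discarded as shared with copies could lower them, but 53.9% of the KRT14 sequence occurs in no other gene, and scaled for this its level was 0.177% of KRT5. Cells that lack the basal program would lack its other genes too, but 20 of 22 basal genes had at least 10 CPM. KRT14 itself was one of the 2 below that level. No other cell type was measured, so the level does not tell basal keratinocytes from other epithelial cells. KRT7, KRT13 and KRT19 averaged 1835, 5664 and 1999 CPM over the 6 libraries. Whether the cells are HaCaT, as labelled, was not tested, and the cause of the low counts stays open.

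A planned hypothesis was that transcripts with denser GGACU motifs, a sequence favoured by m6A, in the 3-prime UTR rise when the reader is reduced. Across 10851 genes, which are not independent replicates, the partial Spearman correlation of motif density with log2 fold change was 0.0041 (permutation p = 0.667, 10000 permutations). Without adjustment for 3-prime UTR length and GC content, expression level and transcript length, the Spearman correlation was 0.0262. The median log2 fold change was 0.01 in 3848 genes without the motif and 0.05 in the 2172 with the densest motif. The adjusted test thus gave no relation with motif density. Methylation itself was not measured here, so the test does not speak for methylated transcripts.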
